A study of Homo sapiens with 22 samples.

How the data were processed

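Chromatin accessibility was measured by ATAC-seq in CD8+ T cells sorted from the blood of people with ME/CFS and of healthy sedentary controls. Per the labels' protocols, CD3+ cells were enriched from mononuclear cells and live CD56- CD8+ cells were sorted as naive (CD45RA+ CCR7+) or antigen-experienced (CD45RA-, with or without CCR7), and a modified Omni-ATAC protocol was used. The series text names 7 ME and 7 healthy donors, of whom 6 and 6 were analysed here. The 22 libraries formed 4 groups: 6 naive healthy, 6 naive ME, 5 experienced healthy and 5 experienced ME libraries. Each replicate within a group came from a separate donor. The titles placed 10 donors in both populations and 2 donors in the naive population alone. By the titles, naive ME replicate 6 and experienced ME replicate 5 came from the same donor, so a pair need not share a replicate number.

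The deposited table held raw counts, one value per accessible region and library, over 1 shared set of 67189 peaks with a median width of 446 bp (range 132 to 2708 bp). The submitters' processing notes named hg38, Bowtie2 2.4.5, Picard 2.26.1, SAMtools 1.18, MACS3 3.0.0b1 and featureCounts of Subread 2.0.3, without their roles or settings. Whether peaks were called on pooled or single libraries, how they were merged, how duplicates were treated and whether reads or fragments were counted was not stated in those notes. Positions are given as the table has them, on hg38, and whether they count from 0 or from 1 was not stated.

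Only the 65335 autosomal peaks were analysed, and the 1854 peaks on chromosome X were left out so that no result could follow a donor's sex. Peaks were assigned to protein-coding genes of the RefSeq annotation of GRCh38.p14: a peak whose midpoint lay inside a gene went to that gene, and any other peak to the gene with the nearest end within 100 kb. This placed 32384 peaks inside genes and 18894 outside them, and left 14057 unassigned. The annotation used here carried no strand or exons, so the design's nearest transcription start site was replaced by this rule, and promoters by gene ends, meaning peaks within 1 kb of either end of a gene (13027 peaks). The counts of all peaks of a gene were summed to 1 value per gene locus (14346 loci), which held 226 of the 256 genes of the lists below. PDCD1 had no locus and was not analysed here.

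Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr, prior count 2), with Benjamini-Hochberg adjusted p below 0.05 as the threshold, on peaks and on loci. The 5 comparisons were ME against healthy in naive cells, ME against healthy in experienced cells, experienced against naive in healthy donors, experienced against naive in ME donors, and the interaction of disease and population in 1 fit of all libraries. Fold changes are on the log2 scale with their standard error, and levels are counts per M (CPM) as mean ± SD over the libraries of a group. In each direction the peaks named were the 10 with the smallest p among those that passed, 1 per gene, whose group medians differed in the same direction. Where fewer than 5 passed, up to 5 with the smallest p were named as not passing. For each gene list up to 4 members with the smallest p at the locus were eligible, and 13 immune genes fixed in advance were followed in every comparison. Peaks in the MHC (chromosome 6, 25 to 34 Mb) and at immunoglobulin, T cell receptor, KIR and LILR genes were not named. CCR7 and the CD45RA antigen served in the sort and count as no finding.

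The 21 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM of loci, with adjustment over the lists of a comparison, and list medians and means are on that scale. They covered naive and stemness genes, cytotoxic effectors, inhibitory receptors, exhaustion transcription factors, effector and memory transcription factors, AP-1 and early activation, cytokines, chemokines and homing, the interferon response, glycolysis, fatty acid oxidation and mitochondria, NK receptors on T cells, the cell cycle, the CD8 lineage, CD4 lineage markers, B cell markers, monocyte markers, NK cell markers, MAIT and innate-like T markers, platelet and erythroid markers, and housekeeping controls. A memory axis was computed per library as the mean log2 CPM of peaks higher in experienced cells minus that of peaks lower in them, over peaks called in the same direction in both disease groups. Single values per library were compared by exact two-sided permutation tests. Relations across libraries were tested by permutation tests with adjustment over 5 relations, and group differences of library measures with adjustment over 24 tests.

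The comparisons, lists, named-gene rule and a set of other settings were chosen before the data were examined. The other settings fixed at that stage were RLE size factors, total counts, trended (loess, span 0.3) offsets on peaks, no filter, DESeq2 1.42.0, 1 surrogate variable (sva 3.50.0), a fit of all 4 groups, a replicate block, an estimated correlation or fry for the lists, gene-end peaks alone, a 2 kb window, an axis over the top 2000 peaks and leaving out each library. The paired design rests on the titles: the replicate block was the donor for the population comparisons and the interaction, and the correlations of the 2 libraries of a donor, after removal of group means, ran from -0.478 to 0.771 in healthy and from 0.345 to 0.879 in ME donors. For the disease comparisons the block was the replicate number, for which the labels give no meaning. Libraries of different donors with the same number, 1 healthy and 1 ME, had such correlations from -0.129 to 0.806 in naive cells. In experienced cells these ran from -0.155 to 0.731. The correlations within donors therefore do not by themselves show the pairing, and replicate numbers carry structure of unknown source. Settings added after the data had been seen were a batch term for replicates 1 to 3 against 4 to 6, fits within each of these sets, fits without the 5 libraries of lowest background, assignment to the nearest gene end alone, trended offsets on loci, lists and the axis, an exact permutation test of list means, and exact sign-flip tests of the first component and of background within donors. Corrections for GC content and the planned motif scores were not run, since no genome sequence was used here.

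Autosomal counts per library ran from 3.625 to 153.8 M. Reads amplified by PCR without molecular identifiers are not independent molecules, so any precision read from these counts covers counting error only. The spread between donors was carried by the SD and by the tests. Counts were simulated from fits with trended offsets, using the dispersions of those fits. Each peak's group effect was set to 0 before changes were put in. The offsets stayed in the simulated counts, so trends that differ between groups remained, and the setting favours trended offsets. Peaks were drawn independently, so structure shared between peaks beyond the offsets was absent. In the disease comparisons and the interaction, fewer real than unchanged simulated peaks had an unadjusted p under 0.05 with TMM (212, 764 and 369 against 1496, 1582 and 1661). Recovery in the real libraries may therefore be lower than in the simulated counts. On these counts the edgeR test with TMM scaling recovered 0 of 100 peaks changed 2-fold and 30 of 100 changed 4-fold in naive ME against healthy. In experienced ME against healthy it recovered 0 and 31. It recovered 1 and 27 of 100 in the healthy population comparison, 0 and 27 in the ME one and 0 and 7 in the interaction, and it made 1, 1, 5, 2 and 0 false calls. With trended offsets it recovered 14 and 33, 9 and 32, 8 and 39, 11 and 37, and 3 and 21 of 100 in these comparisons, with 0, 3, 6, 3 and 1 false calls. A shift of 0.5 (log2) put into 1 list of 15 loci was estimated at 0.53 and called, with 0 other lists called. The loci were drawn independently of each other, so this simulation cannot show how often correlated loci give false list calls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.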

Results

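Accessible chromatin of sorted CD8+ T cells was profiled in 22 ATAC-seq libraries, in a study whose title asks whether these cells are primed towards exhaustion in ME/CFS. Naive cells came from 6 healthy and 6 ME donors and antigen-experienced cells from 5 healthy and 5 ME donors, with 10 donors in both populations. Autosomal counts in peaks averaged 24.3 ± 15.3 M per naive healthy library (SD, range 3.63 to 47.2 M) and 46.3 ± 54.5 M per naive ME library (14.3 to 153.8 M). They averaged 39.6 ± 17 M per experienced healthy library (21.03 to 61.9 M) and 64.1 ± 37.2 M per experienced ME library (27.2 to 115.4 M). The difference in totals between ME and healthy libraries did not pass an exact two-sided permutation test in naive (p = 0.478, adjusted p = 0.917) or experienced cells (p = 0.222, adjusted p = 0.735).

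The main axes of variation went with cell population and library background. The second principal component (18.9% of variance) separated experienced from naive libraries in healthy donors and in ME donors (exact permutation p = 0.00216 in each, adjusted p = 0.0259 over 24 tests), and ME and healthy libraries did not part on the first 3 components (adjusted p from 0.917 to 0.984). The first component (56.8%) followed background, taken as the CPM of the 10th percentile peak, with Pearson's r = -0.846 (permutation p = 1e-05, adjusted p = 2.5e-05 over 5 relations) and Spearman's rho = -0.95 (permutation p = 1e-05, the smallest the permutations can give). Without the 2 libraries farthest from the median background r was -0.946. In 9 of the 10 donors with both populations the experienced library was higher on the first component (mean difference 146 ± 191, SD, exact two-sided sign-flip p = 0.00586, adjusted p = 0.00977 over 2 tests) and lower in background (-0.41 ± 0.731 CPM, exact p = 0.00977, adjusted p = 0.00977), so background was not balanced between the populations. The third component (4.39%) parted the 12 libraries with replicate numbers 1 to 3 (1.73 to 80.2) from the 10 with numbers 4 to 6 (-162.4 to -15.4). Both disease groups and both populations were in each set. The sets were drawn after this separation was seen, so its permutation p of 3e-05, unadjusted over the measures compared, only restates it. Within the sets, background and the first component had r = -0.96 and r = -0.92.

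**Figure D1:**
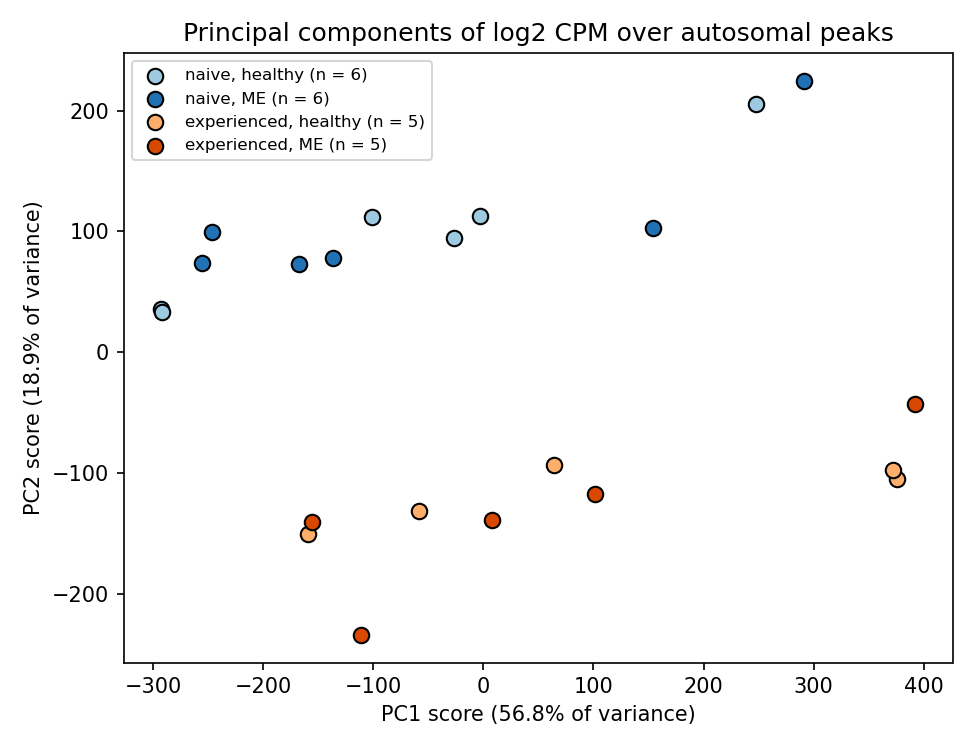
Principal components of log2 CPM over autosomal peaks, first component (56.8% of variance) on the horizontal and second (18.9%) on the vertical axis, 1 point per library, marked by cell population and disease group. Naive libraries lie at 33.7 or above on the second component and experienced libraries at -42.4 or below, with ME and healthy libraries intermixed.

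The comparison of experienced with naive cells in healthy donors gives the reference for a change of state in these cells. The list of naive and stem-like T cell genes was less accessible in experienced cells (n = 5) than in naive cells (n = 6), with 9 of 15 loci passing, and the lists of cytotoxic effectors (8 of 15) and of effector transcription factors (8 of 12) were more accessible. These 3 calls did not hold in camera with an estimated correlation between loci (adjusted p = 0.256, 0.256 and 0.137). They held with fry (adjusted p = 0.00102, 0.00142 and 8e-05), which called 12 lists in this comparison. ACTN1, which encodes an actin cross-linker, fell by 1.95 ± 0.18 (SE) on the log2 scale, from 164 ± 8.1 to 42.5 ± 13.6 CPM (SD), and LEF1, a transcription factor of naive T cells, fell by 1.51 ± 0.23. NKG7, a protein of cytotoxic granules, rose by 2.41 ± 0.26, from 10.2 ± 4.12 to 54.0 ± 7.12 CPM. TBX21, which encodes the effector regulator T-bet, rose by 1.35 ± 0.14, from 32.5 ± 5.13 to 82.5 ± 12.4 CPM.

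Of the 15 naive and stemness loci in healthy donors 0 rose, 9 fell and 6 did not pass (10 fell adjusted over the list alone). The list fell with a median of -0.68 (camera adjusted p = 7.33e-07, adjusted p = 0.256 with an estimated correlation). Besides ACTN1 and LEF1, the adhesion receptor gene PECAM1 fell by 1.09 and the chromatin organiser gene SATB1 by 0.68. Of the 15 cytotoxic effector loci 8 rose and 0 fell (12 rose adjusted over the list alone). The list rose with a median of 1.09 (adjusted p = 5.74e-07, adjusted p = 0.256 with an estimated correlation). CST7, which encodes a cathepsin inhibitor, rose by 1.94, the pore-forming protein gene PRF1 by 1.1 and the protease gene GZMB by 1.31. Of the 12 effector and memory transcription factors 8 rose and 0 fell (9 rose adjusted over the list alone). The list rose with a median of 0.85 (adjusted p = 8.72e-08, adjusted p = 0.137 with an estimated correlation). KLF6 rose by 1.04, BHLHE40 by 1.87 and ZNF683 by 0.99. Of the 15 exhaustion transcription factors 5 rose and 2 fell (7 and 2 adjusted over the list alone). This list rose with a median of 0.39 (adjusted p = 0.00942, adjusted p = 0.256 with an estimated correlation). NFATC2, a calcium-activated factor, rose by 1.62, MAF by 1.87 and the AP-1 factor BATF by 0.77. NFATC1, a relative of NFATC2, fell by 0.59. AP-1 and early activation rose with a median of 0.23 (adjusted p = 0.00522, adjusted p = 0.311 with an estimated correlation), and 4 of its 15 loci were higher (5 adjusted over the list alone). With each library left out in turn its median ran from 0.108 to 0.256, and the call was kept. FOSL2 rose by 0.81, the interleukin receptor gene IL2RA by 0.69 and ATF3 by 0.48. The cell cycle list rose with a median of 0.19 (adjusted p = 0.0112, adjusted p = 0.311 with an estimated correlation), and 2 of its 14 loci were higher (3 adjusted over the list alone). The mitotic checkpoint gene BUB1 rose by 0.55 and the replication gene MCM2 by 0.43. With trended offsets the exhaustion transcription factors (adjusted p = 0.0674), AP-1 (0.0912) and cell cycle lists (0.0912) were no longer called. With gene-end peaks alone the effector and memory transcription factors had a median of 0.09 (adjusted p = 0.196) and were not called, nor were the exhaustion transcription factors, AP-1 and the cell cycle (0.116 each), while the cytokines were called upward (0.0205). Within replicates 1 to 3 the exhaustion transcription factors had adjusted p = 0.000776 and within replicates 4 to 6 adjusted p = 0.0461. AP-1 had 0.0724 and 0.00112 in these sets, and the cell cycle list 0.0724 and 0.0187.

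The inhibitory receptors were mixed in healthy donors: 5 of 14 loci rose and 2 fell (5 and 2 adjusted over the list alone). The list was not called (adjusted p = 0.355; test upward, median -0.10, mean -0.01). TIGIT, which encodes an inhibitory receptor for poliovirus receptor family ligands, rose by 1.60 ± 0.19, from 47.7 ± 14.7 to 144 ± 17.7 CPM. LAG3, an inhibitory receptor that binds MHC class II, rose by 0.98 ± 0.15, from 26.2 ± 5.66 to 51.5 ± 3.73 CPM. TNFRSF9, which encodes the costimulatory receptor CD137, rose by 2.05, and LAYN, a hyaluronan receptor gene, fell by 2.57. Of the other genes followed in every comparison, TOX (0.60 ± 0.28, adjusted p = 0.181), PRDM1 (0.39 ± 0.14, 0.0798), IFNG (0.25 ± 0.18, 0.402), TCF7 (-0.05 ± 0.11, 0.798), EOMES (-0.14 ± 0.22, 0.705), CTLA4 (-0.29 ± 0.37, 0.634), HAVCR2 (-0.57 ± 0.51, 0.491) and IL7R (-0.30 ± 0.15, 0.204) did not pass. TOX and IL7R passed without naive healthy replicate 4 (adjusted p = 0.0468 and 0.029), and PRDM1 without naive healthy replicate 1 (0.0179). IL7R also passed with trended offsets and PRDM1 by DESeq2. With each library left out in turn, HAVCR2 ran from -1.29 to -0.222, CTLA4 from -0.557 to -0.0917 and IFNG from 0.0637 to 0.338. These 3 loci did not pass in any of these fits. CCR7, which served in the sort, had 248 ± 48.7 CPM in naive and 267 ± 37.8 CPM in experienced libraries.

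In healthy donors 4504 peaks rose and 3723 fell of 64701 tested (12.7% called, median size 1.91 on the log2 scale), as did 885 and 1061 of 14278 loci. Named peaks that rose were assigned to ATP9B, RYR1, GALM, SYNE1, AP1S3, SETBP1, EEF1G (1356 bp outside the gene), NID1 and PPP1R16B. They rose by 3.19 (SETBP1) to 4.90 (GALM), with adjusted p from 1.31e-05 to 1.59e-05. At ATP9B, a lipid flippase gene (chromosome 18, 79245572 to 79246769, inside the gene), accessibility was 4.68 ± 1.43 CPM in naive and 48.4 ± 10.3 CPM in experienced libraries. The lowest experienced library (39.1) was above the highest naive one (7.2). The 10 named peaks that fell were assigned to NRCAM, ALPK1, MTRF1, CPA6, RASSF8, MICAL2, ZFYVE28, HADH, FBXL18 and ZNF496. Those of RASSF8, CPA6 and HADH lay 98044, 20952 and 1366 bp outside the gene. The 10 peaks fell by 2.76 (FBXL18) to 5.24 (MICAL2), with adjusted p from 1.31e-05 to 3.55e-05. At the end of NRCAM, a cell adhesion gene (chromosome 7, 108456244 to 108457055), accessibility was 21.1 ± 4.45 CPM in naive and 1.15 ± 0.436 CPM in experienced libraries. The median over all peaks was -0.31 with TMM, -0.63 with total counts and -0.08 with trended offsets. The share of called peaks that were higher was 54.7%, 38.6% and 62.1%, so the balance of directions is relative to the scaling. Within replicates 1 to 3 and within replicates 4 to 6, 1089 and 2607 peaks were called, of which 1080 and 2549 were also called with all libraries. In the paired fit with the donor as replicate block 8026 peaks and 1868 loci were called. Without the 5 libraries of lowest background there were 5325 peaks and 884 loci, and without experienced healthy replicate 2 there were 1279 loci.

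The same comparison in ME donors asks whether their cells pass through the same change. In ME donors the naive and stemness list was less accessible in experienced cells (n = 5) than in naive cells (n = 6), with 12 of 15 loci passing, and the lists of cytotoxic effectors (10 of 15) and effector transcription factors (10 of 12) were more accessible. In camera with an estimated correlation the first of these calls held (adjusted p = 0.00846) and the others did not (0.313 and 0.123). With fry all 3 were called (adjusted p = 5.41e-07, 0.00346 and 0.000154). ACTN1 fell by 1.97 ± 0.16, from 165 ± 8.98 to 42.4 ± 11 CPM, and LEF1 by 1.61 ± 0.16. NKG7 rose by 2.4 ± 0.27, from 11 ± 3.78 to 59.1 ± 18.2 CPM, and TBX21 by 1.56 ± 0.15, from 30.9 ± 5.77 to 92.2 ± 10.8 CPM. TOX, a factor of exhausted T cells, rose by 1.19 ± 0.29 (adjusted p = 0.0103), from 95.7 ± 30.5 to 221 ± 96.7 CPM. IL7R, the receptor for a survival cytokine, fell by 0.46 ± 0.10 (adjusted p = 0.00597).

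Of the 15 naive and stemness loci in ME donors 0 rose and 12 fell (12 adjusted over the list alone). The list fell with a median of -0.62 (camera adjusted p = 1.14e-07), a call that held with an estimated correlation (adjusted p = 0.00846). BACH2, a repressor that keeps T cells quiescent, fell by 0.88 and PECAM1 by 0.85. Of the 15 cytotoxic loci 10 rose and 0 fell (11 adjusted over the list alone). The list median was 1.24 (adjusted p = 1.18e-07, adjusted p = 0.313 with an estimated correlation). The migration receptor gene S1PR5 rose by 2.25, CST7 by 2.32, PRF1 by 1.30 and GZMB by 1.48. Of the 12 effector and memory transcription factors 10 rose and 0 fell (10 adjusted over the list alone). Their list median was 0.67 (adjusted p = 3.36e-07, adjusted p = 0.123 with an estimated correlation). BHLHE40 rose by 1.89, KLF6 by 1.13 and ZEB2 by 1.77. Of the 15 exhaustion transcription factors 7 rose and 2 fell (8 and 2 adjusted over the list alone). Their list rose with a median of 0.28 (adjusted p = 0.0121, adjusted p = 0.366 with an estimated correlation). NFATC2 rose by 1.81, MAF by 2.18, the Notch partner gene RBPJ by 0.72 and BATF by 0.85. Of the 10 cytokine loci 4 rose and 0 fell (6 adjusted over the list alone). The cytokine list rose with a median of 0.89 (adjusted p = 0.0207, adjusted p = 0.472 with an estimated correlation). The growth factor gene CSF2 rose by 2.30, IL13 by 2.11, IL4 by 2.48 and IL17A by 2.21. AP-1 and early activation rose with a median of 0.18 (adjusted p = 0.0483, adjusted p = 0.366 with an estimated correlation), and 4 of its 15 loci were higher (5 adjusted over the list alone). FOSL2 rose by 0.78, IL2RA by 0.57 and ATF3 by 0.40. The inhibitory receptors were mixed (5 of 14 higher and 1 lower, 5 and 2 adjusted over the list alone) and not called (adjusted p = 0.209; test upward, median -0.05, mean 0.16). TIGIT rose by 1.80 ± 0.23, from 49.2 ± 16.4 to 174 ± 30.8 CPM. LAG3 rose by 1.00 ± 0.12, from 25.7 ± 2.82 to 52.0 ± 4.56 CPM. TNFRSF9 rose by 2.32 and LAYN fell by 2.18. The AP-1 call was lost without naive ME replicate 2 (adjusted p = 0.0516), 4 (0.0564) or 5 (0.0714), at medians of 0.158, 0.19 and 0.15. Without experienced ME replicate 2 (0.0635) or 5 (0.0874) it was lost at medians of 0.193 and 0.215. It was also lost in the paired fit with the donor as replicate block (0.0946) and within replicates 1 to 3 (0.0765). The cytokine call was lost without experienced ME replicate 2 (0.088). With gene-end peaks alone the effector and memory transcription factors had a median of 0.29 (adjusted p = 0.194) and were not called, nor were the exhaustion transcription factors (0.0741) and AP-1 (0.585), while chemokines and homing were called upward (0.0164). With trended offsets the exhaustion transcription factors had adjusted p = 0.0529 and AP-1 adjusted p = 0.261. Within replicates 1 to 3 and 4 to 6 the exhaustion transcription factors had 0.00325 and 0.0404, and the cytokines the same pair of values.

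PRDM1, which encodes the effector regulator Blimp, rose by 0.38 ± 0.12 in ME donors (adjusted p = 0.046). The call was lost without any 1 of naive ME replicates 1, 2, 3, 4 and 6 and experienced ME replicates 1, 2, 4 and 5 (adjusted p up to 0.106). IFNG (0.49 ± 0.19, adjusted p = 0.102), TCF7 (-0.14 ± 0.10, 0.35), EOMES (0.19 ± 0.19, 0.529), CTLA4 (-0.16 ± 0.21, 0.663) and HAVCR2 (-0.59 ± 0.32, 0.237) did not pass. IFNG passed without experienced ME replicate 3 (adjusted p = 0.0418), and its value ran from 0.199 to 0.616 with each library left out in turn. EOMES and HAVCR2 passed in the paired fit with the donor as replicate block.

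In ME donors 5299 peaks rose and 5771 fell of 64769 tested (17.1% called, median size 1.88), as did 1243 and 1507 of 14292 loci. The 10 named peaks that rose were assigned to ATP9B, GALM, SPTB, MCPH1, ADHFE1, UBE2E3, SLC2A8, AKAP13, CHD9 and ANXA6. Those of UBE2E3 and ANXA6 lay 99962 and 6508 bp outside the gene. The 10 peaks rose by 2.36 (CHD9) to 4.40 (SPTB), with adjusted p from 1.9e-05 to 6.37e-05. The ATP9B peak was the one named in healthy donors and rose by 3.09 ± 0.24, from 4.37 ± 0.977 to 40.8 ± 9.98 CPM. The 10 named peaks that fell were assigned to XRCC5, ABLIM1, PXDC1, EVA1A, UBAC2, CREB5, NDNF, BCL2L11, SSX2IP and PNPLA8. Some lay outside the gene: PXDC1 (98960 bp away), EVA1A (75378), SSX2IP (31750), UBAC2 (27132), NDNF (25734) and PNPLA8 (6648). The 10 peaks fell by 3.03 (NDNF) to 5.09 (BCL2L11, which encodes a death-promoting protein), with adjusted p from 3.52e-06 to 1.21e-05. In XRCC5, a DNA repair gene (chromosome 2, 216120014 to 216120601), accessibility was 11.4 ± 1.59 CPM in naive and 0.488 ± 0.102 CPM in experienced libraries. The median over all peaks was -0.26 with TMM, -0.48 with total counts and -0.05 with trended offsets. The share of called peaks that were higher was 47.9%, 37.7% and 57.6%. The balance also depended on single libraries: the share ran from 44.6% without naive ME replicate 2 to 62.8% without naive ME replicate 3, where 8564 peaks were higher and 5081 lower. Without naive ME replicate 6 there were 7651 higher and 4950 lower. Within replicates 1 to 3 and within replicates 4 to 6, 830 and 6698 peaks were called, of which 823 and 6280 were also called with all libraries. In the paired fit with the donor as replicate block 19926 peaks (9578 higher and 10348 lower) and 5194 loci were called. Among these peaks 11066 were also called without the block.

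**Figure D2:**
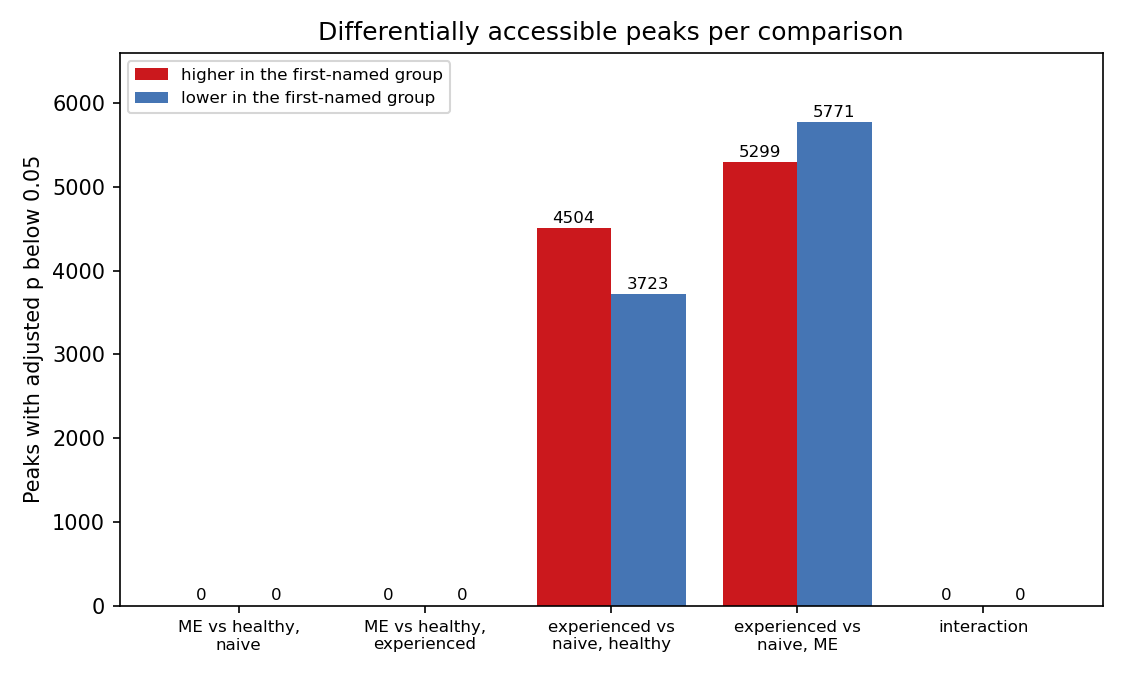
Number of peaks with adjusted p below 0.05 in each comparison (vertical axis, peaks), with bars for peaks that were higher and lower in the first-named group. Healthy donors had 4504 higher and 3723 lower peaks in experienced cells and ME donors 5299 and 5771, and the ME against healthy comparisons and the interaction had 0.

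Healthy and ME donors shared most of the population difference, and these 2 comparisons have no library in common. Of the 64580 peaks tested in both, 3644 rose and 3304 fell in both, and 0 were called in opposite directions. If the calls were independent 369 and 332 would be shared. The fold change had the same sign in ME donors for 99.94% of the peaks called in healthy donors. Across peaks, which are not independent replicates, the fold changes had r = 0.899.

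**Figure D3:**
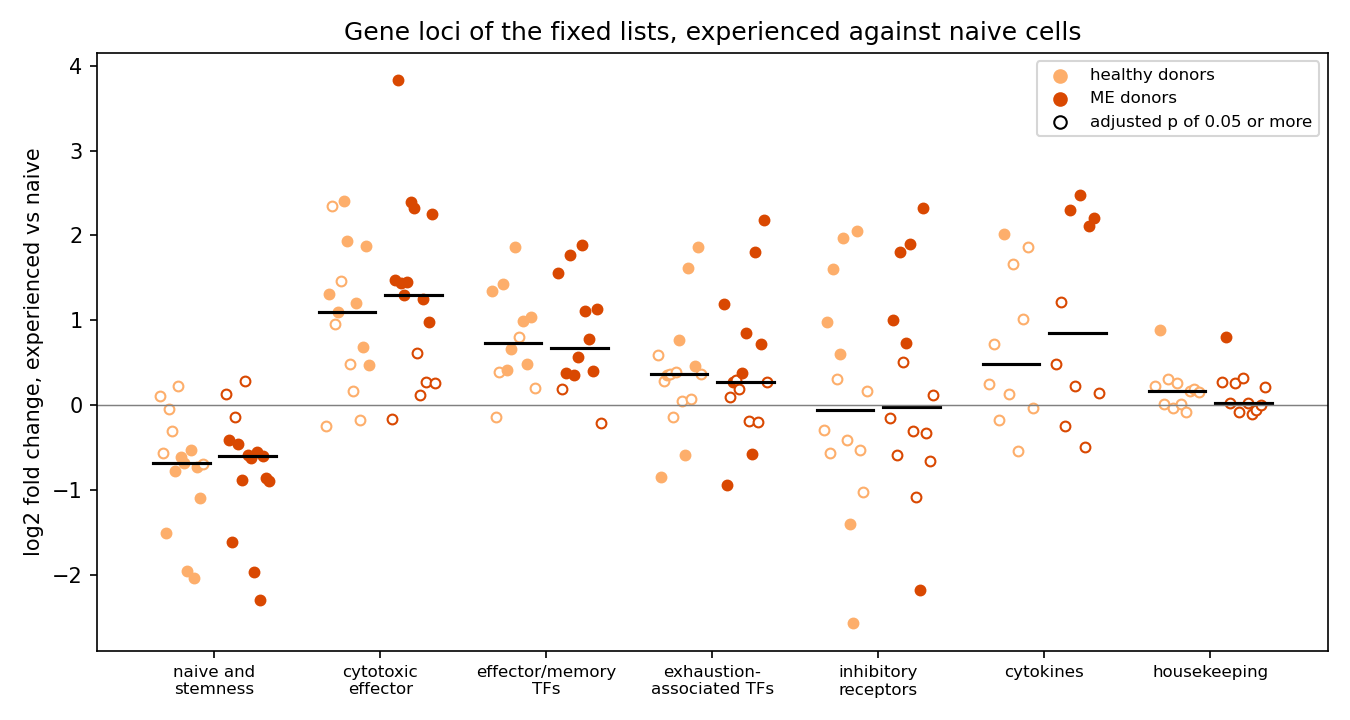
Log2 fold change of experienced against naive cells at the loci of 7 gene lists (vertical axis), 1 point per locus in healthy and in ME donors, filled where the adjusted p was below 0.05 and open otherwise, with a bar at the median of the plotted values. Naive and stemness loci lie mostly below 0, cytotoxic loci and effector transcription factors mostly above 0, and inhibitory receptors on both sides, from -2.57 for LAYN to 2.05 for TNFRSF9 in healthy donors.

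The comparison of ME with healthy donors in naive cells (n = 6 and 6) asks whether the cells differ before they meet antigen. The genes of inhibitory receptors and exhaustion factors did not pass the test in this comparison. TOX had 95.7 ± 30.5 CPM in ME and 99.4 ± 45.7 CPM in healthy libraries (log2 fold change -0.04 ± 0.30). TIGIT had 49.2 ± 16.4 and 47.7 ± 14.7 CPM (0.06 ± 0.25), and LAG3 25.7 ± 2.82 and 26.2 ± 5.66 CPM (-0.02 ± 0.16). Of the other fixed genes, CTLA4 (-0.07 ± 0.24), HAVCR2 (-0.19 ± 0.33), TCF7 (0.05 ± 0.11), TBX21 (-0.06 ± 0.16), EOMES (-0.09 ± 0.24), PRDM1 (-0.01 ± 0.14), GZMB (0.00 ± 0.24), IFNG (0.13 ± 0.11) and IL7R (-0.05 ± 0.13) also had an adjusted p of 1. Adjusted over the list alone each of the 12 genes had 0.987. The cell cycle list was the one list called, with 0 of 14 loci passing and 13 above 0. It rose with a median of 0.09 (camera adjusted p = 0.0268, adjusted p = 0.961 with an estimated correlation). BUB1 had 0.17 ± 0.09 and MCM2 0.18 ± 0.11. The mean log2 CPM of its loci was 5.89 ± 0.118 in ME and 5.79 ± 0.115 in healthy libraries (exact permutation p = 0.173). The cell cycle call was lost without naive healthy replicate 3 (median 0.102, adjusted p = 0.058), 4 (median 0.0514, 0.425) or 6 (median 0.0832, 0.102). It was lost without naive ME replicate 2 (median 0.0508, 0.294), 3 (median 0.0841, 0.482) or 6 (median 0.115, 0.12). It was also lost with gene-end peaks alone (0.533), with trended offsets (0.162), within replicates 1 to 3 (median 0.09, 0.146) and within replicates 4 to 6 (median 0.11, 0.202), where fewer libraries gave medians no smaller than with all libraries. In the other 20 lists 0 loci passed, over all loci or adjusted over the list alone. Their adjusted p ran from 0.158 (chemokines and homing, and monocyte markers) to 0.981. Leaving out 1 library added a call for the CD8 lineage and housekeeping lists without naive healthy replicate 4 (both downward, adjusted p = 0.0295) and for chemokines and homing without naive ME replicate 5 (downward, 0.0331). With all libraries and an estimated correlation these lists had 0.987, 0.987 and 0.961. The test, the median and the mean of the log2 fold changes differed in sign for the cytotoxic, effector transcription factor, interferon, NK receptor, CD8, CD4, NK cell and housekeeping lists.

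With edgeR 0 of 64042 peaks and 0 of 14244 loci passed between naive ME and healthy cells. At an unadjusted p under 0.05 there were 212 peaks and 54 loci. A uniform p would give 3202 peaks. On simulated counts, a separate set of 63442 tested peaks that included 100 changed 2-fold and 100 changed 4-fold, 1496 unchanged peaks had such a p. DESeq2 called 0 peaks and 0 loci, with 497 peaks at an unadjusted p under 0.05. The peaks with the smallest p, none of which passed (adjusted p = 1), lay near NID1, STK40, CIZ1, LOC124901868 and LDHC among those above 0 and near EXOC5, LOC107986768, PDXK, MAPK1IP1L and FAM174A among those below 0. The peak nearest to EXOC5, which encodes a part of the exocyst (chromosome 14, 57112295 to 57112752), had -2.61 ± 0.55, at 0.351 ± 0.221 CPM in ME and 2.06 ± 0.905 CPM in healthy libraries. On simulated counts 0 of 100 peaks changed 2-fold and 30 of 100 changed 4-fold were recovered in this design with TMM scaling, and 14 and 33 with trended offsets. The simulated peaks were independent of each other, and recovery in the real libraries may be lower.

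The comparison in experienced cells (n = 5 and 5) asks whether ME donors differ after antigen encounter. The list of MAIT and innate-like T cell markers was lower in ME donors, with 7 of 8 loci below 0 and 0 passing (0 adjusted over the list alone). The list fell with a median of -0.20 and a mean of -0.33 (camera adjusted p = 0.00551, adjusted p = 0.328 with an estimated correlation). ZBTB16, the master regulator of innate-like T cells, had 148 ± 43.9 CPM in ME and 233 ± 95.5 CPM in healthy libraries (-0.66 ± 0.27). The chemokine receptor gene CCR6 had 57.0 ± 24.4 and 99.2 ± 44.3 CPM (-0.81 ± 0.36). KLRB1, which encodes CD161, had -0.20 ± 0.19. The mean log2 CPM of the 8 loci was 5.53 ± 0.296 in ME and 5.86 ± 0.255 in healthy libraries (exact permutation p = 0.0952). The MAIT call rested on part of the libraries: within replicates 1 to 3 the list had a median of -0.44 (adjusted p = 0.000268) and within replicates 4 to 6 a median of 0.06 (adjusted p = 0.975). It was lost without experienced healthy replicate 1 (median -0.11, adjusted p = 0.108), experienced ME replicate 3 (median -0.11, 0.361) or experienced ME replicate 5 (median -0.18, 0.0761), with gene-end peaks alone (median -0.29, 0.498) and without the 5 libraries of lowest background (median -0.26, 0.133).

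The exhaustion and inhibitory receptor genes did not pass between experienced ME and healthy cells. TOX had 221 ± 96.7 CPM in ME and 149 ± 35.8 CPM in healthy libraries (0.56 ± 0.26, and 0.30 without experienced ME replicate 2). TIGIT had 174 ± 30.8 and 144 ± 17.7 CPM (0.27 ± 0.12), and LAG3 52.0 ± 4.56 and 51.5 ± 3.73 CPM (0.01 ± 0.11), each with an adjusted p of 1. Adjusted over the list alone, TOX, TIGIT, EOMES (0.25 ± 0.14) and IL7R (-0.20 ± 0.11) had 0.292. CTLA4 (0.07 ± 0.35), HAVCR2 (-0.20 ± 0.51), TCF7 (-0.04 ± 0.10), TBX21 (0.16 ± 0.13), PRDM1 (-0.01 ± 0.11), GZMB (0.17 ± 0.24) and IFNG (0.38 ± 0.25) had 0.377 to 0.93. The value of IFNG was 0.10 without experienced ME replicate 2. In the 20 lists other than the MAIT list 0 loci passed, over all loci or adjusted over the list alone. Their adjusted p ran from 0.115 to 0.975. CD4 lineage markers had the lowest of these (median -0.15, mean -0.29), with adjusted p = 0.0471 with trended offsets, 0.0255 without experienced healthy replicate 3 and 0.0349 without experienced ME replicate 2. The CD4 list was also called with the replicate block by number. With an estimated correlation this list had 0.328, and 0.278 with trended offsets as well. CCR8, a chemokine receptor gene, had -1.33 ± 0.55. Without experienced ME replicate 1 the cytotoxic (0.0364) and CD8 lineage lists (0.0283) were called upward, and with all libraries and an estimated correlation both had 0.913. The test, the median and the mean differed in sign for the exhaustion transcription factors (test downward, median -0.03, mean 0.01) and the platelet and erythroid markers (test downward, median 0.03, mean -0.06).

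With edgeR 0 of 64493 peaks and 0 of 14276 loci passed between experienced ME and healthy cells. At an unadjusted p under 0.05 there were 764 peaks and 201 loci. A uniform p would give 3225 peaks, and among the 63928 peaks tested on simulated counts 1582 unchanged ones had such a p. DESeq2 called 1 peak (1229 at an unadjusted p under 0.05) and 3 loci, which were chosen for naming after their values were seen. RABL2A, a small GTPase gene, held the peak (-1.87, adjusted p = 0.00774) and was 1 of the loci (-1.83, adjusted p = 2.17e-10). The others were the centrosome gene CEP72 (-0.62, adjusted p = 0.00683) and SNED1, a matrix protein gene (-1.01, adjusted p = 0.0266). In edgeR RABL2A had 4.39 ± 0.788 CPM in ME and 15.6 ± 3.72 CPM in healthy libraries (-1.83 ± 0.24, adjusted p = 0.0853, and 0.0247 with 1 surrogate variable). The gene has a near-identical copy, RABL2B, so the placement of its reads is uncertain. The peaks with the smallest p, none of which passed in edgeR (adjusted p = 1), lay near LDHC, IL26, CIROZ, DMRTB1 and S1PR1 above 0 and near RABL2A, PRKCA, GIMAP4, ARFGEF2 and GLB1 below 0. The peak nearest to the cytokine gene IL26 (chromosome 12, 68181003 to 68181548) had 11.3 ± 1.17 CPM in ME and 6.19 ± 0.905 CPM in healthy libraries (0.82 ± 0.21). A peak in PRKCA, a protein kinase C gene (chromosome 17, 66374227 to 66374734), had 10.1 ± 4.91 and 44.4 ± 22.4 CPM (-2.25 ± 0.49). On simulated counts 0 of 100 peaks changed 2-fold and 31 of 100 changed 4-fold were recovered in this design with TMM scaling, and 9 and 32 with trended offsets. The simulated peaks were independent here too, and recovery in the real libraries may be lower.

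**Figure D4:**
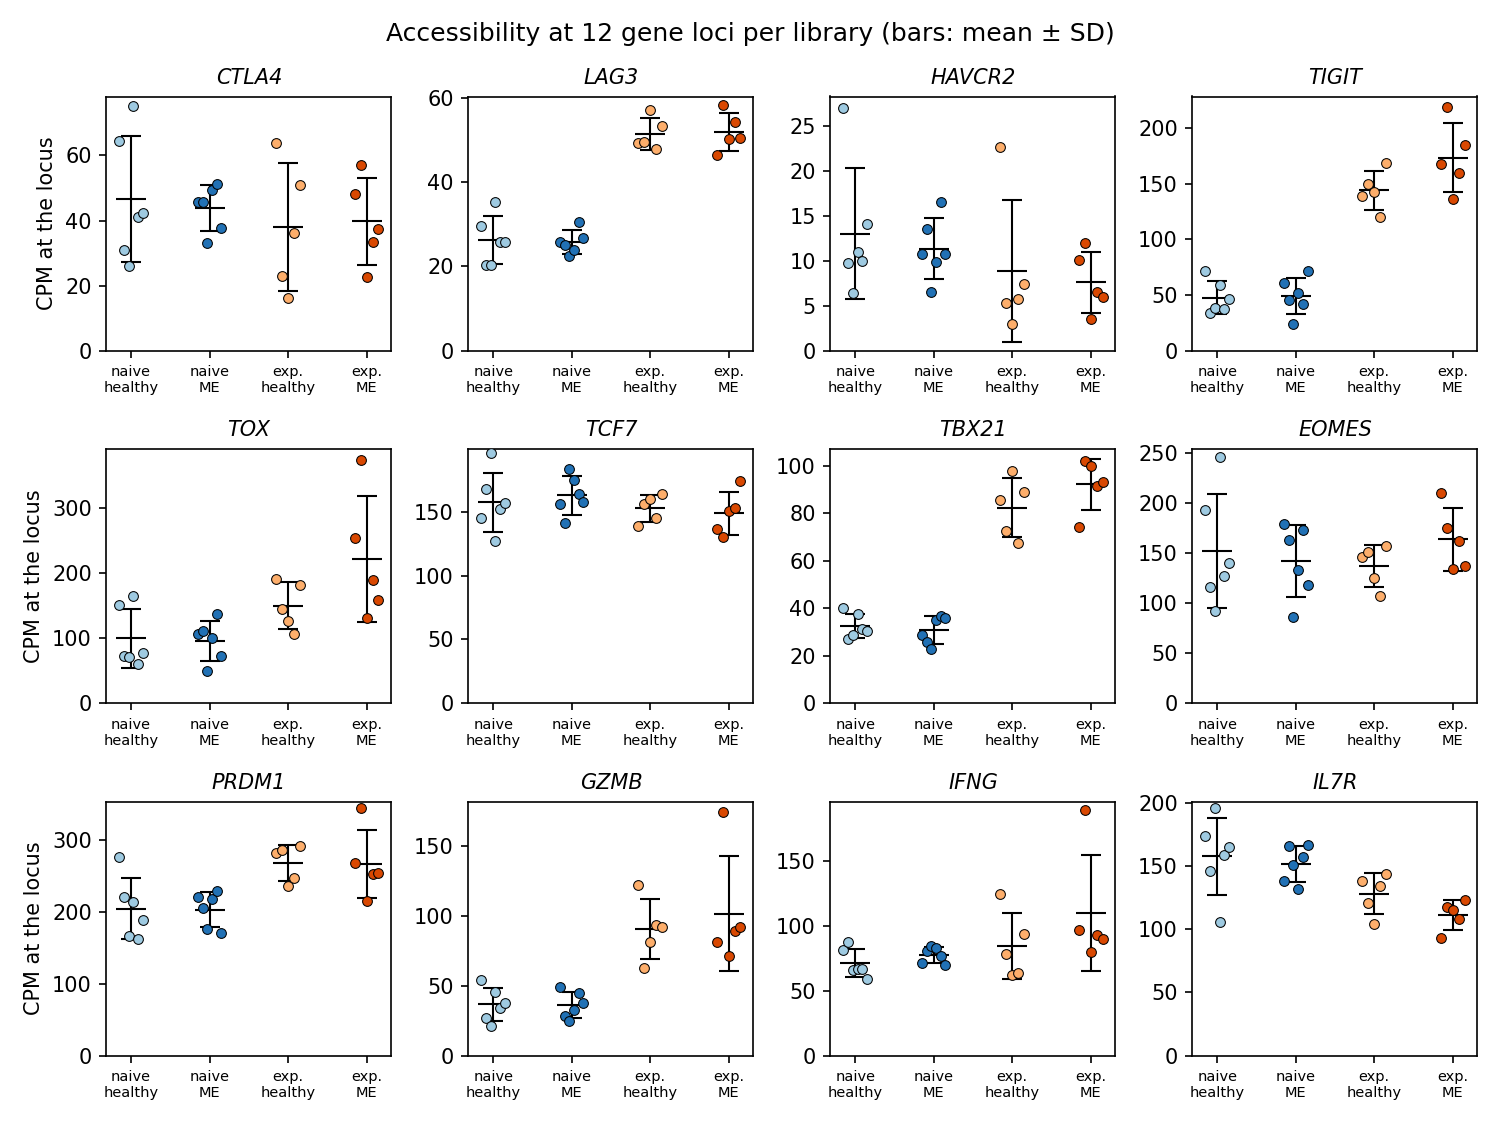
Accessibility in CPM (vertical axes, summed over the peaks of a gene) at 12 immune genes fixed in advance, 1 point per library in the 4 groups, with the mean and SD of each group. TIGIT lies at 47.7 and 49.2 CPM in naive healthy and naive ME cells and at 144 and 174 CPM in experienced healthy and experienced ME cells.

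The interaction asks whether the step from naive to experienced differs between ME and healthy donors. Inhibitory receptors had a median difference of 0.21 (11 of 14 loci above 0, adjusted p = 0.155), cytotoxic effectors 0.17 (13 of 15 above 0, adjusted p = 0.171) and cytokines 0.23 (9 of 10 above 0, adjusted p = 0.162). No locus of any list passed, over all loci or adjusted over the list alone, and 0 of the 21 lists was called (adjusted p from 0.155 to 0.944). TOX had 0.61 ± 0.43 (0.34 without experienced ME replicate 2), TIGIT 0.22 ± 0.31, LAG3 0.03 ± 0.18, TBX21 0.23 ± 0.20, EOMES 0.35 ± 0.31, GZMB 0.18 ± 0.36, IFNG 0.26 ± 0.28, CTLA4 0.15 ± 0.44, PRDM1 0.00 ± 0.19, HAVCR2 -0.01 ± 0.62, TCF7 -0.08 ± 0.14 and IL7R -0.15 ± 0.18, each with an adjusted p of 1. In the paired fit with the donor as replicate block the cytotoxic, inhibitory receptor and cytokine lists were called upward and the cell cycle list downward, each with adjusted p = 0.0496. Without the block the same 4 lists had adjusted p from 0.155 to 0.171, and from 0.85 to 0.879 with an estimated correlation. The paired fit was not run with an estimated correlation. It called 0 peaks, with 1300 at an unadjusted p under 0.05. Leaving out 1 library also gave calls: the MAIT list downward without naive healthy replicate 1 (adjusted p = 0.00579) or 4 (0.00901), naive ME replicate 3 (0.00883), experienced ME replicate 2 (0.0288) or experienced healthy replicate 4 (0.046). CD4 lineage markers were called downward without naive healthy replicate 4 (0.0447), naive ME replicate 3 (0.0338) or experienced ME replicate 2 (0.0417). The CD8 lineage was called upward without naive healthy replicate 4 (0.0116) and the cell cycle list downward without experienced ME replicate 2 (0.0279). With all libraries and an estimated correlation the MAIT, CD4 and CD8 lists had 0.85, 0.802 and 0.899. Within replicates 1 to 3 the cytotoxic (0.0117) and CD8 lineage lists (0.0117) were called upward and the MAIT list downward (0.0147), and within replicates 4 to 6 0 lists. The test, the median and the mean differed in sign for the exhaustion, effector transcription factor, fatty acid oxidation, NK cell and platelet lists. With edgeR 0 of 65166 peaks (369 at an unadjusted p under 0.05) and 0 of 14326 loci (92) passed, and DESeq2 called 0 peaks (634) and 0 loci. On simulated counts the interaction test recovered 0 of 100 peaks changed 2-fold and 7 of 100 changed 4-fold with TMM scaling, and 3 and 21 with trended offsets. The peaks with the smallest p, none of which passed (adjusted p = 1), included those near the cytokine genes IL21 (2.72 ± 0.80) and IL26 (0.77 ± 0.23) and near NEB and TOP1MT above 0. Below 0 were peaks in ANXA2, a membrane-binding protein gene (-1.20 ± 0.32), and HK1, a hexokinase gene (-1.17 ± 0.32), and near SUSD4, ABTB2 and MB21D2.

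Naive cells of ME donors were also compared with healthy ones along the axis from naive to experienced cells, over the 3644 peaks higher and 3304 lower in experienced cells of both disease groups. A peak had to be called in both disease groups to enter the axis, so a shift that ended either call would be missed. The axis value was -1.01 ± 0.486 in naive ME and -0.92 ± 0.318 in naive healthy libraries, a difference of -0.09 (exact permutation p = 0.714; the smallest possible is 0.00216). In experienced cells it was 3.43 ± 0.599 in ME and 3.36 ± 0.513 in healthy libraries, a difference of 0.06 (exact permutation p = 0.873; the smallest possible is 0.00794). The difference changed sign without naive ME replicate 3 in naive cells (0.04), and in experienced cells without healthy replicate 1 (-0.03) or 5 (-0.06) or ME replicate 2 (-0.18). The share of counts at gene ends was 61.8% ± 3.71 in naive ME and 60.5% ± 6.47 in naive healthy libraries (exact permutation p = 0.688), and 64.5% ± 2.68 and 64.4% ± 3.4 in experienced libraries (exact permutation p = 0.976). Its difference changed sign without naive healthy replicate 4 (-0.757 percentage points), and in experienced cells without healthy replicate 1 (-1.3) or 5 (-0.00665) or ME replicate 3 (-0.871) or 4 (-0.268).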

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

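The test of a smooth trend behind the first component, the comparison of the component and of background within donors, the tests of background and of a few donors for the MAIT list, the test of a different population difference in ME donors and all values with trended offsets on lists, without the 5 libraries of lowest background or within replicates 1 to 3 or 4 to 6 were chosen after the result was seen.

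In 68 checks, each of 1 library measure or fixed locus within 1 group of 5 or 6 libraries, 4 found a library far from the others. The nominal rate of the rule gives 3.4, although the checks reuse the same libraries and are not independent. The HAVCR2 locus, which encodes the inhibitory receptor TIM-3, had 22.7 CPM in experienced healthy replicate 1, and the nearest library of its group had 7.38 CPM. In experienced ME replicate 2 the GZMB locus had 174 CPM, with 92.2 CPM in the nearest library, and the IFNG locus 188 CPM, with 96.4 CPM in the nearest. Naive ME replicate 6 had 154 M autosomal counts, and the nearest naive ME library had 52.4 M.

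The list of MAIT and innate-like T cell markers was lower in experienced ME cells (median -0.20, camera adjusted p = 0.00551, adjusted p = 0.328 with an estimated correlation). Chance cannot be excluded, since 71 of 100 splits of these libraries, the real one included, called at least 1 list. Within replicates 4 to 6 the median of the MAIT list was 0.0555 (camera adjusted p = 0.975). A smooth trend of background was argued against as the whole source, since with trended offsets the median was -0.195 (camera adjusted p = 0.00998). With an estimated correlation as well the list had 0.278. These offsets left the first component at an absolute Spearman correlation of 0.905 with background, so other effects of background stay open. Without the 5 libraries of lowest background the median was -0.26 and the call was lost (adjusted p = 0.133). The call may rest on a few donors: without experienced ME replicate 3 the median was -0.11 (adjusted p = 0.361) and without experienced healthy replicate 1 it was -0.11 (0.108), while without experienced ME replicate 5 the call was lost (0.0761) at a median of -0.18. A candidate explanation is a smaller share of MAIT-like cells among the sorted cells of those donors, where the CD56- gate of the sort would remove the MAIT cells that carry CD56. For 8 further MAIT genes, fixed before their values were seen (ABCB1, ADAM12, CEBPD, COLQ, IL18RAP, LTK, ME1 and TMIGD2, 1 of them also in the NK cell list), the median was -0.402 and 6 were below 0, the direction that explanation predicts, although their mean did not pass (exact permutation p = 0.302), with 137 ± 47.7 CPM in healthy and 130 ± 33.6 CPM in ME libraries at ABCB1, the most accessible of them.

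The first principal component (56.8% of variance) spread the libraries by background, and in 9 of 10 donors the experienced library was higher on it than the naive one (exact two-sided sign-flip p = 0.00586, adjusted p = 0.00977 over 2 tests) and had the lower background (p = 0.00977, adjusted p = 0.00977). Total counts (log2) followed the component too (Pearson's r = 0.526, permutation p = 0.0111; Spearman's rho = 0.673, permutation p = 0.00083; both unaltered by adjustment over 5 relations; r = 0.448 without the 2 farthest libraries). Unequal depth was argued against as the whole source: after every library was thinned to 3.625 M counts the absolute Spearman correlation of the component with background was 0.958 and its share of variance 46.5%. A smooth trend of background on mean accessibility was argued against as the whole source, since with offsets that remove it the correlation was 0.905 and the share 40.4%. A part of the spread went with cell population within donors, and whether the cells or their preparation set the background stays open.

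ME donors had more peaks called between experienced and naive cells (11070) than healthy donors (8227). The shallowest library, naive healthy replicate 4, was argued against as the whole source, since without it the healthy count was 8941. It may account for a part, since leaving out any other healthy library lowered the count (6348 to 8203). The order held in the paired fit (19926 and 8026) and within replicates 4 to 6 (6698 and 2607) and reversed within replicates 1 to 3 (830 and 1089). The 2 libraries of a donor correlated from -0.478 to 0.771 in healthy and from 0.345 to 0.879 in ME donors, so the donor block may gain less in healthy donors. Mean totals were higher in naive and experienced ME libraries (46.31 and 64.11 M) than in healthy ones (24.25 and 39.63 M). Whether this depth adds to the order was not tested. A different population difference in ME donors cannot be told apart from equal differences with unequal spread. The interaction test called 0 peaks with edgeR (369 at an unadjusted p under 0.05) and 0 by DESeq2. The paired interaction fit also called 0 peaks (1300 at an unadjusted p under 0.05), but 4 gene lists at the preset correlation. On simulated counts the unpaired test recovered 0 of 100 peaks changed 2-fold and 7 of 100 changed 4-fold.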

How the results depend on the processing

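Alternatives chosen after seeing the data were the batch term for replicates 1 to 3 against 4 to 6, fits within these sets, fits without the 5 libraries of lowest background, nearest gene ends, trended offsets on loci, lists and the axis, and the exact test of list means; corrections for GC content, alone or with the block, and motif scores were not run. The 0 peaks and 0 loci of naive ME against healthy and of the interaction were the same under every alternative run. The named peaks were run with RLE size factors, total counts, trended offsets, DESeq2, the replicate block and each library left out, and kept their directions and calls there, except for RABL2A in experienced cells (-1.87, adjusted p = 0.00774 by DESeq2). Over all results and alternatives other than single genes and lists, 349 values were classed as kept, 62 as moved and 10 as reversed. A count of calls was classed as kept if it stayed at 0 or within a fixed ratio of the main count. Neither the direction of the calls nor which peaks, loci or lists were called entered that class. For single genes and lists, 2469 values kept their direction and call, 65 became weaker, 9 stronger and 87 reversed. In experienced ME against healthy 1 peak and 3 loci were called by DESeq2, 1 locus with 1 surrogate variable and 9 peaks within replicates 4 to 6. Experienced against naive in healthy donors gave 12618 peaks and 3255 loci with 1 surrogate variable, 1089 and 79 within replicates 1 to 3, 2607 and 0 within replicates 4 to 6, and 5325 and 884 without the 5 libraries of lowest background. In ME donors it gave 18992 and 4530 with 1 surrogate variable, 19926 and 5194 in the paired fit with the donor as replicate block, 830 and 248 within replicates 1 to 3, and 6698 and 962 within replicates 4 to 6. Smaller sets of libraries leave fewer residual degrees of freedom; for the other changes the cause was not tested. Lists called in naive ME against healthy (1) numbered 0 with gene-end peaks, an estimated correlation, fry, trended offsets, without the 5 libraries of lowest background, within replicates 4 to 6 and by the exact test, and 2 within replicates 1 to 3 (chemokines and homing, and the CD8 lineage, both downward). Those in experienced ME against healthy (1) numbered 0 with gene-end peaks, an estimated correlation, fry, without the 5 libraries of lowest background, within replicates 4 to 6 and by the exact test, and 2 with trended offsets or the replicate block by number, the added list being CD4 lineage markers. Lists in healthy donors (6) numbered 3 with gene-end peaks, 0 with an estimated correlation and 12 with fry, those in ME donors (6) 1 with an estimated correlation, and those in the interaction (0) 4 with the replicate block by donor, 1 without the 5 libraries of lowest background and 3 within replicates 1 to 3. The MAIT list reversed within replicates 4 to 6 (0.0555), and the share at gene ends in experienced cells within 2 kb (-0.0048); the cause was not tested. Small differences also changed sign for single loci: in naive ME against healthy LAG3 (0.00701 with trended offsets, 0.00369 with the replicate block by number), CTLA4 (0.00413), PRDM1 (0.00709) and GZMB (0.0188) with that block; in experienced cells LAG3 (-0.0107 with total counts) and HAVCR2 (0.0231 with that block); in the interaction PRDM1 (-0.00471 with total counts) and HAVCR2 (0.10 with trended offsets, 0.19 with the replicate block by donor). With each library left out in turn, these loci changed sign: in naive ME against healthy CTLA4 -0.20 to 0.0995, LAG3 -0.085 to 0.075, HAVCR2 -0.35 to 0.14, TOX -0.18 to 0.15, PRDM1 -0.0637 to 0.0928, GZMB -0.13 to 0.14, TIGIT -0.0739 to 0.20, IL7R -0.15 to 0.0147, TBX21 -0.13 to 0.016, EOMES -0.205 to 0.0862, TCF7 -0.0083 to 0.12; in experienced ME against healthy LAG3 -0.0269 to 0.0602, HAVCR2 -0.42 to 0.50, PRDM1 -0.11 to 0.0668, CTLA4 -0.12 to 0.33, TCF7 -0.0943 to 0.0142, GZMB -0.11 to 0.29; in experienced against naive in healthy donors TCF7 -0.0908 to 0.0227, EOMES -0.25 to 0.0551; in experienced against naive in ME donors CTLA4 -0.32 to 0.0276; in the interaction PRDM1 -0.105 to 0.0761, HAVCR2 -0.33 to 0.71, CTLA4 -0.0431 to 0.415, LAG3 -0.0567 to 0.12, GZMB -0.105 to 0.31, IFNG -0.0333 to 0.435. Over the left-out libraries the loci called in healthy donors ran from 1279 to 2287, the lists called from 0 to 2 in naive ME against healthy, from 0 to 3 in experienced ME against healthy and from 0 to 3 in the interaction, the difference in the memory axis from -0.234 to 0.0393 in naive and from -0.184 to 0.237 in experienced cells, and the difference in the share at gene ends from -0.757 to 2.6 and from -1.3 to 0.948 percentage points. Depth limits these comparisons in the shallowest library, which had 3.63 M counts.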

Other observations

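The shares of called peaks by position and the correlation of disease effects between populations were computed after the data had been seen, and the counts over other splits of the libraries were planned.

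Metabolic genes and receptors moved in part with the population. In healthy donors 4 of 17 glycolysis loci rose and 1 fell (5 and 1 adjusted over the list alone; list adjusted p = 0.186): the lactate exporter gene SLC16A3 rose by 0.83 ± 0.15, LDHA, which makes lactate, by 0.40 ± 0.08 and PKM by 0.53 ± 0.14, and HK2, a hexokinase gene, fell by 0.69 ± 0.16. In ME donors 4 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.41; test upward, median 0.11, mean -0.01), with HK2 lower by -1.19 ± 0.15, SLC16A3 higher by 0.71 ± 0.15 and the glucose transporter gene SLC2A1 by 0.43 ± 0.11. Of 12 loci of fatty acid oxidation and mitochondria, 1 rose and 1 fell in healthy donors (1 and 1 adjusted over the list alone; adjusted p = 0.232) and 3 rose and 1 fell in ME donors (3 and 1 adjusted over the list alone; adjusted p = 0.201). The thiolase gene ACAA2 rose by 0.67 ± 0.14 and 0.93 ± 0.18, and PPARGC1B, a regulator of mitochondrial genes, fell by 0.74 ± 0.13 in healthy and by 0.74 ± 0.15 in ME donors. Of the chemokine and homing loci 3 of 13 rose and 0 fell in healthy donors (3 adjusted over the list alone; adjusted p = 0.0684), with the integrin gene ITGAE at 0.91 ± 0.14, CCR6 at 1.95 ± 0.38 and CCR2 at 1.58 ± 0.35. In ME donors 5 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.0542), with CXCR6 at 1.15 ± 0.31. The cytokine loci had 1 of 10 higher in healthy donors (1 adjusted over the list alone; adjusted p = 0.0935), which was CSF2 at 2.02 ± 0.26, and the cell cycle loci 1 of 14 higher in ME donors (1 adjusted over the list alone; adjusted p = 0.0904), which was BUB1 at 0.44 ± 0.12. Of the interferon response loci 1 rose in each disease group (1 adjusted over the list alone; adjusted p = 0.425 in healthy and 0.461 in ME donors), OASL, an antiviral gene, by 1.67 ± 0.19 and 1.93 ± 0.24.

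Markers of other lineages moved apart from each other between experienced and naive cells, and camera called none of these lists. With fry, B cell markers (adjusted p = 7.47e-05 in healthy and 0.00149 in ME donors) and platelet and erythroid markers (0.00102 and 0.000915) were called. CD4 lineage markers were called by fry in healthy donors (0.0381). The CD4 locus fell by 2.55 ± 0.39 in healthy and by 2.88 ± 0.31 in ME donors, while the lineage regulator gene ZBTB7B rose by 0.46 ± 0.09 in healthy donors (CD4 lineage markers: 2 of 6 higher and 1 lower in healthy donors, 2 and 1 adjusted over the list alone, adjusted p = 0.201; 0 and 1 in ME donors, 0 and 1 adjusted over the list alone, adjusted p = 0.674; test upward, median 0.23, mean -0.29). B cell markers had 0 of 10 higher and 3 lower in each disease group (0 and 4 adjusted over the list alone in healthy donors, 1 and 3 in ME donors; adjusted p = 0.0833 and 0.109), with the B cell factor gene EBF1 lower by -0.55 ± 0.12 and -0.49 ± 0.13. Monocyte markers had 0 of 7 passing in healthy donors (0 and 1 adjusted over the list alone; adjusted p = 0.831; test downward, median -0.22, mean 0.05) and 1 higher, CEBPA at 2.38 ± 0.44, and 1 lower, LYZ at -0.86 ± 0.21, in ME donors (3 and 1 adjusted over the list alone; adjusted p = 0.645; test upward, median -0.27, mean 0.37). NK cell markers had 2 of 5 higher and 1 lower in healthy donors (2 and 2 adjusted over the list alone; adjusted p = 0.837) and 2 higher and 2 lower in ME donors (2 and 3 adjusted over the list alone; adjusted p = 0.606). The Fc receptor genes parted, with FCGR3A at 0.89 ± 0.17 and FCER1G at -2.50 ± 0.52 in healthy donors. The NK receptor list had 1 of 7 higher, KLRD1 at 0.92 ± 0.19, and 1 lower, KLRB1 at -0.55 ± 0.17, in healthy donors (1 and 2 adjusted over the list alone; adjusted p = 0.956; test upward, median -0.01, mean 0.16) and 1 higher and 2 lower in ME donors (1 and 2 adjusted over the list alone; adjusted p = 0.998; test downward, median 0.03, mean 0.16). MAIT and innate-like markers had 2 of 8 higher, CCR6 among them, and 1 lower in healthy donors (3 and 1 adjusted over the list alone; adjusted p = 0.221) and 2 higher and 1 lower in ME donors (3 and 2 adjusted over the list alone; adjusted p = 0.613; test upward, median -0.03, mean 0.16). The CD8 lineage list had 2 of 9 higher, CD2 at 0.56 ± 0.11 and RUNX3 at 0.66 ± 0.13, and 1 lower, CD3G at -0.55 ± 0.15, in healthy donors (3 and 1 adjusted over the list alone; adjusted p = 0.376) and 4 higher and 0 lower in ME donors (4 and 0 adjusted over the list alone; adjusted p = 0.134). Platelet and erythroid markers had 0 of 3 higher and 1 lower in healthy donors, GP9 at -1.29 ± 0.22 (0 and 1 adjusted over the list alone; adjusted p = 0.123), and 0 and 2 in ME donors (0 and 2 adjusted over the list alone; adjusted p = 0.0785). Among housekeeping controls GAPDH alone passed, at 0.89 ± 0.13 and 0.80 ± 0.12 (1 of 11 adjusted over the list alone in each; adjusted p = 0.0935 and 0.113).

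Peaks inside genes were called between experienced and naive cells in 18.9% of cases in healthy and 25.1% in ME donors, peaks outside genes within 100 kb in 15.4% and 20.8%, peaks at gene ends in 7.69% and 10.9%, and peaks farther than 100 kb from a gene in 3.94% and 5.3%. The disease effect in naive cells and that in experienced cells had r = 0.0934 across 63682 peaks, which are not independent replicates, and the same sign in 50% of them.

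Other splits of the libraries into groups of the same sizes show how often a regrouping gives as many calls. The 0 peaks and 0 loci of naive ME against healthy were reached by 100 of 100 splits (highest other 21289 peaks and 3800 loci), and so were those of experienced ME against healthy (100 of 100, highest other 24558 and 1571) and those of the interaction with its 0 lists (100 of 100, highest other 0 peaks, 0 loci and 9 lists). Any split reaches a count of 0, so these counts say nothing about chance. At least the 1 list of naive ME against healthy was given by 54 of 100 splits (highest other 9), and the 1 list of experienced ME against healthy by 71 of 100 (highest other 8), so chance cannot be excluded for either. At an unadjusted p under 0.05, 97 of 100 splits gave at least the 212 peaks of naive ME against healthy (median of the other splits 848), 58 at least the 764 of experienced ME against healthy (829) and 71 at least the 369 of the interaction (502). Of the 32 healthy splits that part as many donor pairs as the real one, only it gave 8227 peaks or more (highest other 1774). The same held for 1946 loci or more (highest other 29). Of 32 ME splits only the real one gave 11070 peaks or more (highest other 2820) and 2750 loci or more (highest other 416). The smallest share that 32 splits can give is 0.0312, so first place among them does not by itself exclude chance. Other splits did reach the number of lists. In healthy donors 12 of 32 gave 6 lists or more (highest other 10), and in ME donors 10 of 32 (highest other 9). The other 68 splits of each population comparison part fewer donor pairs, and 2 of them in healthy donors (highest 15087) and 1 in ME donors (27815) called more peaks than the real split. In naive and experienced ME against healthy 2 of 100 splits each called more than 5000 peaks. All of these large splits put the 3 libraries of lowest background on 1 side, which points to a structure of the libraries by background, although most of the 16, 14, 15 and 16 splits of the 4 comparisons that did so called 5000 peaks or fewer.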
